A study of Mus musculus with 20 samples.

How the data were processed

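The values analysed were whole-number estimated counts per transcript, made by the authors before they were deposited. Per the submitters' processing notes, reads were checked with FastQC 0.11.8, aligned to GRCm38 with HISAT2 and assembled and counted with StringTie, and edgeR 3.34.0 was used for testing. Versions of HISAT2 and StringTie are not given in the sources used here. The estimated counts held no fractions, so no rounding was needed. Of 142699 transcripts, 141469 were matched to the GENCODE M21 annotation of GRCm38 and summed to 55260 genes, and the 1230 others held at most 0.40% of the counts of a library. Ribosomal RNA made up 0.7 to 1.69% of counts and mitochondrial genes 0.75 to 1.9%. Raw reads were not used here.

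Analyses were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genes were kept by edgeR's filterByExpr at a minimum count of 10 and a minimum total of 15. Counts were normalised by TMM and tested with edgeR's quasi-likelihood F-test, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with 0.05 as the limit. Standard errors were taken as the absolute log2 fold change over the square root of the F statistic, which is approximate.

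The 18 tested comparisons were 3 between populations with the treatment pool as a term, 4 of irradiated pools against the untreated pool, 4 of anti-SIRPa and 4 of anti-PD-1 within the irradiated pools, and 3 interactions with population. The tests of an antibody had 1 residual degree of freedom. Comparisons of the triple combination with other single treatments had 1 library on each side and were given as ratios without a test. These used a prior count of 2, genes at 10 CPM or more in either library, and 10000 random lists drawn from 20 bins of expression. Ranked single-library genes had at least 20 CPM and 50 counts, and the 95% intervals covered counting error only. The comparisons, their models, the gene lists and most alternatives were fixed before the data were examined.

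Altogether 36 lists were tested with camera at a preset correlation of 0.01, and again with the correlation estimated from the residuals. Lists with fewer than 3 measured genes were left out of a comparison. Adjusted p-values of lists were taken over the lists of a comparison. The number of members that passed was counted over all genes tested and, where stated, adjusted over the list alone.

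Genes were named by a rule set before values were read. In each tested comparison these were the 10 genes per direction with the largest absolute log2 fold change among those that passed with at least 10 CPM in 2 libraries, of which the text could print 5. Up to 4 members of each list with the largest change at 10 CPM or more, and the genes Sirpa, Cd47, Pdcd1 and Cd274, were added. For populations the direction had to hold in all 5 pools. Predicted gene models, immunoglobulin and T cell receptor segments and ribosomal pseudogenes were excluded. Results of some genes that the rule names are not reported here. A gene with 0 counts in a whole group was given as a bound against a floor of 3 counts.

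The alternatives were RLE normalisation, no filter on low counts, DESeq2, no pool term, antibody terms in the irradiation test, the other antibody's term dropped, all 20 libraries in 1 fit, and each pool left out in turn. A filter at a mean of 0.5 CPM, removal of the library labelled untreated CD8 T and removal of all CD8 T libraries were added after the data were seen. Single-library ratios were repeated at prior counts of 0.5 and 10, at limits of 1 and 50 CPM, and with CPM by total count alone. Alternatives are named in the results where they change a count more than 1.5-fold or turn the direction of a printed gene, and otherwise in the part on sensitivity.

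The pipeline was tested on simulated data made with 200 changed genes, 50 per fold and direction. Of 100 genes changed 2-fold and 100 changed 4-fold, it recovered 98 and 100 for CD11c+CD11b- against CD11c+CD11b+ cells, 77 and 100 for CD8 T against myeloid cells, 19 and 99 for irradiation in CD11c+CD11b+ cells, 95 and 100 for anti-PD-1 in CD11c+CD11b+ cells, and 26 and 100 for the anti-PD-1 interaction. Among unchanged genes it called 7, 14, 3, 9 and 6. Simulated lists of 20 genes gave camera p-values of 1.58e-45, 5.09e-36, 4.96e-13 and 7.97e-38 when changed and 0.863, 0.0686, 0.446 and 0.295 when unchanged, in the first 4 of these comparisons. Simulated genes were independent, with 1 dispersion for all genes of a comparison and no effects of pools. The simulation thus checked the code and did not measure error rates in the real data, nor could it test the preset correlation.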

Results

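RNA was sequenced from 4 cell populations sorted from MC38-OVA tumours grown in mice, a colon carcinoma line made to express ovalbumin. The populations were CD8 T cells and 3 myeloid fractions defined by the surface integrins CD11c and CD11b, namely CD11c+CD11b+, CD11c+CD11b- and CD11c-CD11b+ cells. CD11c marks dendritic cells and many tumour macrophages, and CD11b marks monocytes, macrophages and granulocytes. Each population came from 5 treatments: untreated (sham-irradiated), radiotherapy alone (RT, 8 Gy given on day 12), RT with an antibody against SIRPa, RT with an antibody against PD-1, and RT with both antibodies. SIRPa is the myeloid receptor for CD47 that restrains phagocytosis, and PD-1 is an inhibitory receptor of activated T cells. Tumours were harvested on day 17, 5 days after irradiation. Each of the 20 groups was 1 library made from the pooled tumours of 10 mice, and the 4 populations of a treatment came from the same pool.

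Library totals ran from 21.5 to 35.7 M (mega) counts, all estimated from reads by the submitters. In the order untreated, RT, RT with anti-SIRPa, RT with anti-PD-1 and RT with both, the CD8 T libraries held 28.2, 21.5, 22.0, 25.3 and 28.1 M. The CD11c+CD11b+ libraries held 28.6, 30.8, 35.7, 26.5 and 34.2 M, the CD11c+CD11b- libraries 30.0, 26.6, 26.0, 22.5 and 24.9 M, and the CD11c-CD11b+ libraries 29.9, 26.2, 25.7, 27.9 and 27.1 M. None of the 190 pairs of libraries was identical, and the closest pair still differed by a chi-square of 13.3 per degree of freedom. No group had a second library, so every test took its spread from differences between treatment pools. The p-values therefore do not measure spread between pools of like treatment, nor between independent experiments. Between populations, the spread is how their difference varied from pool to pool, with any treatment response that differs between them. In the irradiation tests the spread includes antibody effects. In the antibody tests it is the departure from additivity of the antibodies plus spread between pools. Adjusted p-values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, called edgeR adjusted p, and log2 fold changes carry their approximate standard error. Gene lists were tested with camera at a preset correlation between genes, and the value with an estimated correlation follows. Of 535 list tests, 269 passed at the preset correlation and 7 of these passed with an estimated one. The estimate rests on the residuals, with 1 residual degree of freedom for an antibody and 3 for irradiation. How readily a list could pass in those comparisons was not tested, so its loss there decides nothing. Lists were also lost in the population comparisons, which had 4 or 12 residual degrees of freedom. A list that passed only at the preset correlation thus depends on that setting. Gene levels are normalised CPM, given as mean ± SD. Gene positions are on GRCm38.

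The first comparison asked how the CD11c+CD11b- cells differed from the CD11c+CD11b+ cells within each of 5 pools. The CD11c+CD11b- cells carried transcripts of plasmacytoid dendritic cells, NK cells and cross-presenting dendritic cells. Siglech, a plasmacytoid dendritic cell receptor (chromosome 7, 55768178 to 55778925), stood at 117 ± 89.8 CPM against 1.09 ± 0.532 (n = 5 pools each), a log2 difference of 6.44 ± 0.55 (edgeR adjusted p = 0.000125). Dntt, the terminal transferase of lymphoid precursors, differed by 7.17 ± 0.55 (edgeR adjusted p = 7.56e-05). Klk1, a kallikrein, differed by 6.28 ± 0.48 (edgeR adjusted p = 7.59e-05). In the other direction, Sirpa (chromosome 2, 129592835 to 129632228) was at 112 ± 28.7 CPM in CD11c+CD11b- cells against 1070 ± 222 CPM in CD11c+CD11b+ cells (log2 difference -3.27 ± 0.16, edgeR adjusted p = 1.2e-05). The coagulation factor gene F10 was lower by -5.13 ± 0.31 (edgeR adjusted p = 2.6e-05) and Cd300lb, an activating myeloid receptor, by -7.91 ± 0.58 (edgeR adjusted p = 6.33e-05). C5ar2, a receptor for complement C5a, had 0 counts in all 5 CD11c+CD11b- libraries and 16.8 ± 4.93 CPM in the CD11c+CD11b+ libraries, at least 684-fold lower against a floor of 3 counts over the group.

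All 12 macrophage markers were lower in CD11c+CD11b- cells, among them the growth factor receptor Csf1r at a log2 difference of -4.19 and the F4/80 gene Adgre1 at -3.97 (camera adjusted p = 1.78e-15, and adjusted p = 0.153 with an estimated correlation). All 7 neutrophil markers were lower too (camera adjusted p = 1.38e-12, and adjusted p = 0.061 with an estimated correlation). Of 28 type I interferon response genes 26 were lower and none higher, such as the antiviral genes Oas2 at -2.33 and Ifit3 at -2.17 (camera adjusted p = 8.45e-21, and adjusted p = 0.0886 with an estimated correlation). All 18 lysosome genes were lower (camera adjusted p = 5.11e-16, and adjusted p = 0.0978 with an estimated correlation). Of 11 cDC1 markers 5 were higher and 6 did not pass. Those higher included the integrin gene Itgae at 3.32, the dead-cell receptor Clec9a at 2.94 and the chemokine receptor Xcr1 at 2.47 (camera adjusted p = 0.0401, and adjusted p = 0.623 with an estimated correlation). Lymphoid lists were higher as well. Of 7 NK cell markers 6 were higher and 1 lower (camera adjusted p = 1.24e-12, and adjusted p = 0.0886 with an estimated correlation), with the receptor genes Klra8 at 5.25 and Ncr1 at 5.22. Of 12 CD8 T cell markers 11 were higher (camera adjusted p = 2.45e-15, and adjusted p = 0.105 with an estimated correlation). All 23 proliferation genes were higher (camera adjusted p = 2.13e-09, and adjusted p = 0.332 with an estimated correlation). The costimulation list had a median of -0.68 and a mean of 0.11, so its signs differed. In total 8510 of 18727 genes passed edgeR's test, 4326 higher and 4184 lower, with 4 residual degrees of freedom.

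Within the CD11b+ cells, the CD11c+ and CD11c- fractions were compared across the same 5 pools. Relative to each other, the CD11c+CD11b+ cells were higher in genes of mature and conventional dendritic cells, and the CD11c-CD11b+ cells in those of neutrophils. These were not the highest marker lists. In CD11c+CD11b+ cells the mean log2 level was 8.48 to 9.34 for macrophage and 4.36 to 5.66 for cDC2 markers. In CD11c-CD11b+ cells it was 8.53 to 9.22 for inflammatory monocyte and 4.33 to 6.13 for neutrophil markers. Ccl22, a chemokine that draws CCR4-bearing T cells (chromosome 8, 94745590 to 94751699), was at 130 ± 51.0 CPM against 3.63 ± 1.64 (n = 5 pools each), a log2 difference of 5.07 ± 0.36 (edgeR adjusted p = 0.000137). The related chemokine Ccl17 differed by 5.02 ± 0.18 (edgeR adjusted p = 5.54e-06). Ccr7, the receptor that leads dendritic cells to lymph nodes, differed by 4.88 ± 0.30 (edgeR adjusted p = 6.93e-05), and Il12b, a subunit of interleukin 12, by 4.40 ± 0.58 (edgeR adjusted p = 0.00117). The neutrophil genes S100a9 and S100a8 were lower by -3.45 ± 0.37 (edgeR adjusted p = 0.000565) and -3.34 ± 0.33 (edgeR adjusted p = 0.000424), with S100a9 at 578 ± 507 CPM in CD11c-CD11b+ cells. Sirpa was higher in CD11c+CD11b+ cells by 0.75 ± 0.10 (edgeR adjusted p = 0.00123). All 11 MHC class II genes were higher, among them H2-Oa at 3.51 and H2-Eb1 at 2.41 (camera adjusted p = 5.78e-73, and adjusted p = 0.00464 with an estimated correlation). Of 8 cDC2 markers 7 were higher, led by Ccl17 and the lectin gene Mgl2 at 4.16 (camera adjusted p = 4e-28, and adjusted p = 0.0238 with an estimated correlation).

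Of 11 cDC1 markers 9 were higher in CD11c+CD11b+ than in CD11c-CD11b+ cells (camera adjusted p = 2.44e-10, and adjusted p = 0.0253 with an estimated correlation). Of 8 costimulation genes 6 were higher, such as Tnfsf4 at 1.69 and Cd83 at 1.42 (camera adjusted p = 1.29e-09, and adjusted p = 0.0253 with an estimated correlation). Of 12 macrophage markers 11 were higher, with the complement gene C1qa at 1.26 (camera adjusted p = 1.26e-07, and adjusted p = 0.432 with an estimated correlation). All 9 neutrophil markers (camera adjusted p = 3.19e-13, and adjusted p = 0.135 with an estimated correlation) were lower, as were 11 of 12 CD8 T cell markers (camera adjusted p = 1.57e-13, and adjusted p = 0.128 with an estimated correlation). In total 4676 of 18820 genes passed edgeR's test, 2253 higher and 2423 lower. Without the pool as a term the count was 955, and without the RT pool it was 2860.

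CD8 T cells were compared with the mean of the 3 myeloid populations over all 20 libraries. T cell genes were among the largest differences. Cd3e, of the T cell receptor complex, was at 382 ± 214 CPM in the 5 CD8 T libraries against 4.73 ± 3.32 in the 15 myeloid libraries, a log2 difference of 6.68 ± 0.42 (edgeR adjusted p = 1.66e-07). Cd8a (chromosome 6, 71373427 to 71379173) differed by 6.17 ± 0.36 (edgeR adjusted p = 1.6e-07) and Themis, a signalling protein of developing T cells, by 6.75 ± 0.38 (edgeR adjusted p = 1.6e-07). Pdcd1, which encodes PD-1 (chromosome 1, 94038305 to 94052553), was at 240 ± 137 CPM against 7.49 ± 6.08 (log2 difference 5.00 ± 0.35, edgeR adjusted p = 3.57e-07). The NK receptor gene Ncr1 was lower by -3.93 ± 0.41 (edgeR adjusted p = 1.11e-05). Mcpt2, a mast cell protease, had 0 counts in the 5 CD8 T libraries and was at least 141-fold lower against a floor of 3 counts over the group. All 12 CD8 T cell markers were higher (camera adjusted p = 5.89e-40, and adjusted p = 0.0345 with an estimated correlation). Of 16 exhaustion genes, 12 were higher and 2 lower, among them the transcription factor Tox at 4.66 and the inhibitory receptors Ctla4 at 4.14 and Lag3 at 3.76 (camera adjusted p = 1.2e-11, and adjusted p = 0.0348 with an estimated correlation). Of 4 CD4 and regulatory T cell markers 3 were higher (camera adjusted p = 9.1e-06, and adjusted p = 0.0465 with an estimated correlation). All 23 proliferation genes were higher (camera adjusted p = 3.07e-13, and adjusted p = 0.357 with an estimated correlation).

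Of the 12 macrophage markers 0 passed edgeR between CD8 T and myeloid libraries (camera adjusted p = 0.354), and 1 library stood apart in them. The library labelled untreated CD8 T had Cd8a at 48.2 CPM, against 796, 760, 1190 and 1180 CPM in the CD8 T libraries of the RT, RT with anti-SIRPa, RT with anti-PD-1 and RT with both pools. Its C1qa was at 1900 CPM against 296, 262, 120 and 181 CPM. Its 12 CD8 T cell markers lay at 3.93 to 6.64% of the mean of the other 4 libraries. In total 7226 of 20382 genes passed edgeR's test, 3981 higher and 3245 lower, and 10603 passed when that library was removed, a setting added after the data were seen. The count was 4359 without the RT pool, 4492 without the RT and anti-PD-1 pool and 4240 without the pool of both antibodies.

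**Figure D1:**
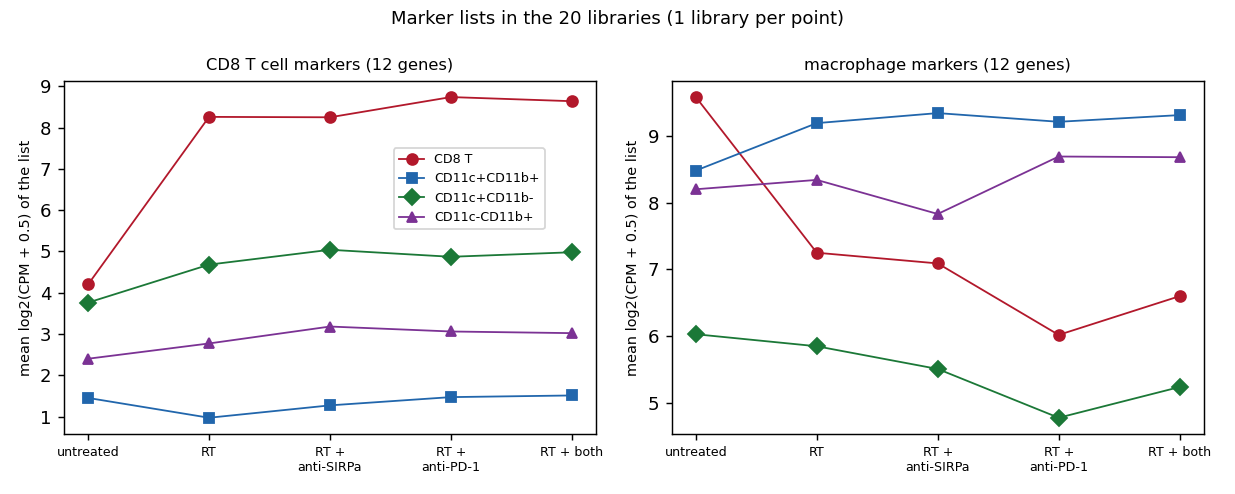
Mean log2(CPM + 0.5) of the 12 CD8 T cell markers (left) and the 12 macrophage markers (right) on the vertical axis, by treatment on the horizontal axis, with 1 point per library and thin lines joining the libraries of a population. The library labelled untreated CD8 T lies at 4.20 for CD8 T cell markers, against 8.25 to 8.74 in the other CD8 T libraries, and at 9.58 for macrophage markers, the highest of the 20.

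The effect of irradiation was tested in each population as the 4 irradiated pools against the single untreated pool, which was assumed to vary as the irradiated pools did. In CD8 T cells this rested on the library labelled untreated CD8 T, whose low CD8 T cell markers and high macrophage markers move with every group named here. Ifng, the interferon gamma gene (chromosome 10, 118441046 to 118445892), was at 533 ± 156 CPM in the irradiated pools (n = 4) against 16.1 in that library, a log2 difference of 5.03 ± 0.49 (edgeR adjusted p = 0.00077). Gzmb, the granzyme B gene (chromosome 14, 56258838 to 56262260), was at 3020 ± 1120 against 94.4 CPM (log2 difference 4.98 ± 0.64, edgeR adjusted p = 0.0018). Pdcd1 was at 297 ± 57.0 against 10.8 CPM (4.76 ± 0.33, edgeR adjusted p = 0.000495). Lower in the irradiated pools were the macrophage elastase gene Mmp12 at -4.14 ± 0.10 (edgeR adjusted p = 4.94e-05), the Fc receptor-like gene Fcrls at -4.96 ± 0.62 (edgeR adjusted p = 0.00163) and Sirpa at -2.70 ± 0.35 (edgeR adjusted p = 0.00187). All 12 CD8 T cell markers were higher (camera adjusted p = 2.63e-27, and adjusted p = 0.212 with an estimated correlation) and all 12 macrophage markers lower (camera adjusted p = 1.48e-14, and adjusted p = 0.239 with an estimated correlation). Of 17 cytotoxicity genes 15 were higher and 2 lower (camera adjusted p = 9.97e-12, and adjusted p = 0.239 with an estimated correlation), and of 16 exhaustion genes 10 were higher (camera adjusted p = 1.13e-08, and adjusted p = 0.285 with an estimated correlation). Of 11 MHC class II genes 10 were lower, with Cd74, the invariant chain, at -3.37 (camera adjusted p = 8.57e-11, and adjusted p = 0.239 with an estimated correlation). In total 5048 of 15855 genes passed edgeR's test, 2351 higher and 2697 lower.

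In CD11c+CD11b+ cells the irradiated pools carried higher levels of interferon-induced genes. The single untreated library differed in other ways too. Its inflammatory monocyte markers had a mean log2 level of 8.63 against 8.14 to 8.19 in the irradiated pools. Mitochondrial genes held 1.355% of its counts against 0.747 to 0.974%. Irradiation was not separated from the make-up of that library. Trex1, a nuclease that degrades cytosolic DNA (chromosome 9, 109057933 to 109059734), was at 73.8 ± 3.63 CPM (n = 4) against 18.6 CPM, a log2 difference of 1.98 ± 0.14 (edgeR adjusted p = 0.0216). Cxcl11, an interferon-induced chemokine (chromosome 5, 92359544 to 92365485), was at 16.9 ± 3.22 against 2.95 CPM (2.51 ± 0.36, edgeR adjusted p = 0.0475). The guanylate-binding protein gene Gbp6 rose by 2.04 ± 0.23 (edgeR adjusted p = 0.0381) and Ly6a, an interferon-induced surface protein, by 1.93 ± 0.18 (edgeR adjusted p = 0.0381). Genes that fell included Enpp2, which makes lysophosphatidic acid, at -3.10 ± 0.42 (edgeR adjusted p = 0.0466), the matrix gene Postn at -2.70 ± 0.21 (edgeR adjusted p = 0.0341) and the macrophage chitinase-like gene Chil3 at -2.20 ± 0.15 (edgeR adjusted p = 0.0216). Enpp2 is 1 of 287 genes that were lower with anti-PD-1 in 3 populations, a group made after results were seen, which held 3.19% of counts untreated and 0.743 to 1.89% in the irradiated pools. Of 28 type I interferon response genes, 8 rose over all genes tested and 26 when adjusted over the list alone, among them Irf7 at 1.31, Oas3 at 1.16 and Rtp4 at 1.14 (camera adjusted p = 4.95e-38, and adjusted p = 0.208 with an estimated correlation). Of 12 macrophage markers 3 rose, and 12 when adjusted over the list alone, with Ms4a7 at 1.53, the high-affinity Fc receptor Fcgr1 at 1.22 and Trem2 at 1.01 (camera adjusted p = 3.5e-19, and adjusted p = 0.208 with an estimated correlation).

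Of 21 measured interferon gamma response genes in CD11c+CD11b+ cells, Cxcl11 rose, and 19 did when adjusted over the list alone (camera adjusted p = 4.52e-17, and adjusted p = 0.313 with an estimated correlation). Of 9 genes of cytosolic DNA sensing, Trex1 rose, and 7 did when adjusted over the list alone (camera adjusted p = 3.84e-08, and adjusted p = 0.208 with an estimated correlation). Of 11 complement genes 3 rose, with Cfb at 1.57 (camera adjusted p = 1.44e-10, and adjusted p = 0.208 with an estimated correlation). The collagen gene Col3a1 differed by -2.39 ± 0.47 and did not pass (edgeR adjusted p = 0.0758), while the stromal and endothelial list had camera adjusted p = 0.0772. In total 147 of 16553 genes passed edgeR's test, 103 higher and 44 lower. The count was 0 without the RT pool, 1 without the pool of both antibodies, 306 without the RT and anti-PD-1 pool and 1910 without the RT and anti-SIRPa pool. DESeq2 passed 1268 genes, edgeR with antibody terms 2342, edgeR with a filter on mean CPM 81 and edgeR with no filter on low counts 4. The fit of all 20 libraries passed 124, of which 42 were among the 147.

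**Figure D2:**
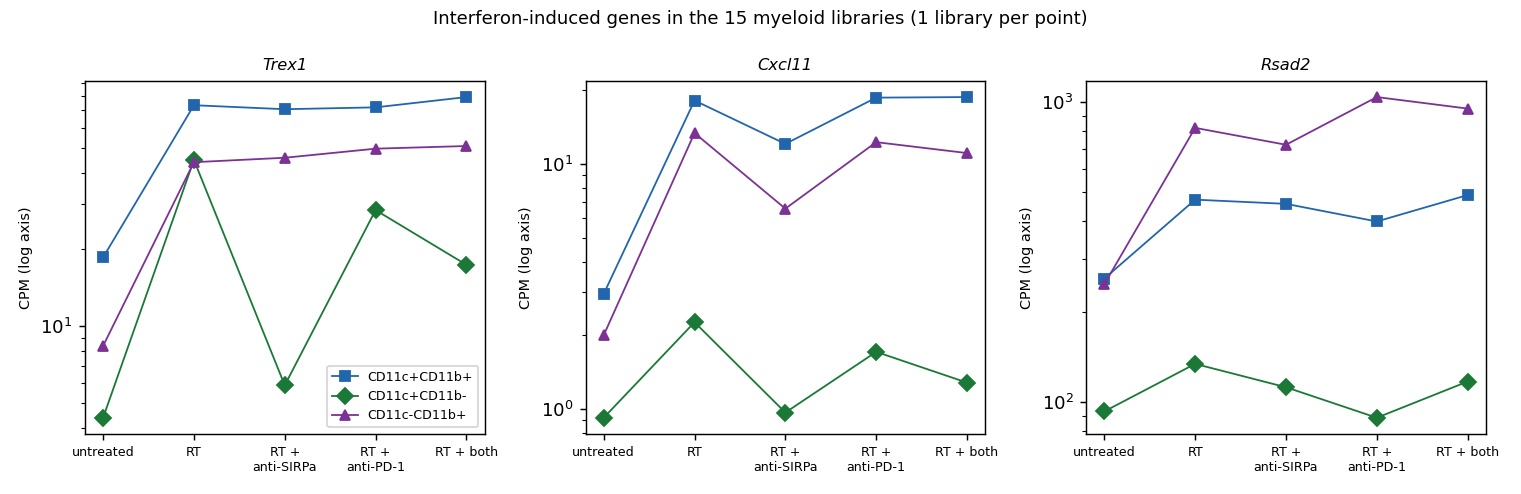
CPM on a log axis of Trex1, Cxcl11 and Rsad2 (vertical) by treatment (horizontal) in the 3 myeloid populations, with 1 point per library and thin lines joining the libraries of a population. In CD11c+CD11b+ cells Trex1 lies at 18.6 CPM untreated and between 70.8 and 79.0 CPM in the 4 irradiated pools.

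In CD11c+CD11b- cells irradiation went with larger differences in dendritic cell genes than passed the test over all genes. Irradiation was not separated from the make-up of the single untreated library. Its CD8 T cell markers had a mean log2 level of 3.76 against 4.68 to 5.04 in the irradiated pools. Calcrl, an adrenomedullin and CGRP receptor (chromosome 2, 84330626 to 84425411), fell by 2.41 on the log2 scale (SE 0.18, 10.3 ± 1.38 CPM with n = 4 against 52.3 CPM, edgeR adjusted p = 0.0499). Rnf150 fell by 2.06 (SE 0.15, edgeR adjusted p = 0.0499), and the last of the 3 genes that passed was a predicted model, so 3 of 16195 genes passed. Among genes that did not pass, Klk1 differed by 4.36 ± 1.05 (edgeR adjusted p = 0.0809), Dntt by 4.12 ± 1.11 (edgeR adjusted p = 0.0906) and Enpp2 by -4.16 ± 0.69 (edgeR adjusted p = 0.0665). The group of 287 genes that includes Enpp2 held 4.42% of counts untreated and 0.595 to 1.77% in the irradiated pools, and in CD11c-CD11b+ cells 4.8% and 1.33 to 3.16%. None of 11 cDC1 markers passed over all genes, and 11 were higher when adjusted over the list alone, with Itgae at 3.07 and Xcr1 at 2.81 (camera adjusted p = 5.39e-09, and adjusted p = 0.461 with an estimated correlation). Of 11 MHC class II genes 10 were higher when adjusted over the list alone (camera adjusted p = 3.95e-07, and adjusted p = 0.461 with an estimated correlation). Of 8 costimulation genes 7 were higher on the same count, with Cd80 at 2.52 and Cd86 at 2.37 (camera adjusted p = 2.38e-06, and adjusted p = 0.461 with an estimated correlation), as were 6 of 7 plasmacytoid dendritic cell markers, with Siglech at 3.65 (camera adjusted p = 0.000455, and adjusted p = 0.461 with an estimated correlation). The CD8 T cell markers moved in the same direction, 6 of 12 on the same count, with Cd8a at 3.10 (camera adjusted p = 7.18e-07, and adjusted p = 0.461 with an estimated correlation). Of 15 immediate early genes 0 passed over all genes and 9 were lower when adjusted over the list alone, with Jun at -1.13 (camera adjusted p = 4.58e-06, and adjusted p = 0.461 with an estimated correlation). At an unadjusted p under 0.05 there were 4212 genes, DESeq2 passed 2674, edgeR with antibody terms 2779, the fit of all 20 libraries 2096 and edgeR with no filter 0. Without the RT and anti-SIRPa pool 3200 genes passed, and 0 passed without the RT pool, the RT and anti-PD-1 pool or the pool of both antibodies.

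For irradiation of CD11c-CD11b+ cells edgeR's test passed 0 of 16733 genes, with 3556 at an unadjusted p under 0.05 and 1400 passing DESeq2. Interferon-induced genes again had large differences, although the largest was that of Gzma. The single untreated library differed in other ways too, with mitochondrial genes at 1.898% of its counts against 0.913 to 1.321% in the irradiated pools. Irradiation was not separated from the make-up of that library. Slfn4, a schlafen family gene, was at 2340 ± 473 CPM (n = 4) against 378 CPM (log2 difference 2.64 ± 0.38, edgeR adjusted p = 0.15), Trex1 differed by 2.51 ± 0.20 (edgeR adjusted p = 0.114) and the antiviral gene Rsad2 by 1.85 ± 0.29 (edgeR adjusted p = 0.15). Gzma, the granzyme A gene (chromosome 13, 113093825 to 113100981), was at 68.5 ± 51.9 against 5.72 CPM (3.60 ± 1.24, edgeR adjusted p = 0.191). Of 28 type I interferon response genes 27 were higher when adjusted over the list alone (camera adjusted p = 7.38e-33, and adjusted p = 0.601 with an estimated correlation), as were 17 of 21 interferon gamma response genes (camera adjusted p = 1.08e-12, and adjusted p = 0.601 with an estimated correlation). Of 16 cytotoxicity genes 15 were higher on the same count, with the perforin gene Prf1 at 2.31 (camera adjusted p = 6.86e-10, and adjusted p = 0.601 with an estimated correlation), and 5 of 12 CD8 T cell markers moved with them (camera adjusted p = 0.000716, and adjusted p = 0.601 with an estimated correlation). Inflammatory monocyte markers moved in the same direction, 4 of 9 on the list alone (camera adjusted p = 0.000627, and adjusted p = 0.601 with an estimated correlation). Without the RT and anti-SIRPa pool 3941 genes passed, and without the RT and anti-PD-1 pool 2. The fit of all 20 libraries passed 646 and a filter on mean CPM 1.

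Whether the response to irradiation differed between the 4 populations was tested with an interaction term over the 20 libraries, and 4207 of 20382 genes passed edgeR's test. The smallest adjusted values belonged to Cd74, H2-Aa, Prf1 and Gzmc, each with edgeR adjusted p = 0.000218, and Sirpa had edgeR adjusted p = 0.000357 and Cd47 edgeR adjusted p = 0.502. Without the CD8 T libraries, and so without the library labelled untreated CD8 T, 169 genes passed, a setting added after the data were seen. With no filter on low counts the count was 2440.

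Anti-SIRPa and anti-PD-1 were each tested within the 4 irradiated pools, 2 with and 2 without the antibody, with the other antibody as a term and 1 residual degree of freedom. Fits with 1 pool left out also dropped the term of the other antibody, so these changes are not separated. In CD8 T cells, few genes passed for anti-SIRPa, and among them were collagen genes. Nedd4, a ubiquitin ligase (chromosome 9, 72662346 to 72749852), rose from 10.0 ± 2.14 to 150 ± 10.1 CPM (n = 2 pools each), a log2 difference of 3.91 ± 0.10 (edgeR adjusted p = 2.61e-06). Neb, the nebulin gene of skeletal muscle, rose by 5.53 ± 0.38 (edgeR adjusted p = 0.0037). Both genes overlap other gene models, and after these were summed their log2 ranges among irradiated libraries were still 3.86 and 6.36, so their counts are treated as uncertain. The collagen VI genes Col6a2 and Col6a1 rose by 1.10 ± 0.08 (edgeR adjusted p = 0.0037) and 0.97 ± 0.07 (edgeR adjusted p = 0.0043), and so did Col3a1 by 0.61 ± 0.07 (edgeR adjusted p = 0.0371), 1 of the 8 stromal and endothelial markers (camera adjusted p = 0.2). These 3 collagen genes belong to the group of 287 genes that were lower with anti-PD-1. Those genes held 1.46% of CD8 T counts with RT and anti-SIRPa against 1.06% with RT, and 0.723% with both antibodies against 0.504% with RT and anti-PD-1, and their share was higher with anti-SIRPa in the 3 myeloid populations too. Mdh1, a malate dehydrogenase, fell by 1.01 (SE 0.14, edgeR adjusted p = 0.0498). Of 23 proliferation genes 12 were lower when adjusted over the list alone, with Mki67 at -0.32 (camera adjusted p = 8.95e-13, and adjusted p = 0.934 with an estimated correlation). Of 17 cytotoxicity genes 7 were lower and 1 higher on the same count, with Gzmb at -0.41 ± 0.08 (camera adjusted p = 3.21e-06, and adjusted p = 0.934 with an estimated correlation). In total 28 of 16486 genes passed edgeR's test, 25 higher and 3 lower, while DESeq2 passed 60 and RLE normalisation 11. A filter on mean CPM passed 28, of which 19 were the same genes. With the other antibody's term dropped 1 gene passed, and with 1 pool left out the count was 10 without the RT pool, 1 without the RT and anti-SIRPa pool, 2 without the RT and anti-PD-1 pool and 0 without the pool of both. The fit of all 20 libraries and the fit with no filter each passed 0. Without the RT and anti-SIRPa pool Col3a1 turned to -0.04, and without the RT and anti-PD-1 pool Gzmb turned to 0.07.

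In CD11c+CD11b+ cells with anti-SIRPa, Evi2b (chromosome 11, 79515056 to 79523762) rose by 1.63 ± 0.09 (edgeR adjusted p = 0.00509), while the gene model Evi2, whose span contains it, fell by 1.37 (SE 0.08, edgeR adjusted p = 0.00509), so neither can be read alone. Mfsd4a, a transporter-like gene, rose by 3.12 ± 0.24 (edgeR adjusted p = 0.0174), Ago1, an effector of microRNAs, by 1.06 ± 0.10 (edgeR adjusted p = 0.0428) and Col6a1 by 0.93 ± 0.11 (edgeR adjusted p = 0.0449). No proliferation gene passed over all genes, and 20 of 23 were higher when adjusted over the list alone, with the kinase gene Aurkb at 0.57 ± 0.11 (camera adjusted p = 1.75e-20, and adjusted p = 0.876 with an estimated correlation). Of 8 cDC2 markers, 3 were lower on the same count, with Ccl17 at -1.26 ± 0.55 (camera adjusted p = 6.74e-05, and adjusted p = 0.876 with an estimated correlation). The mean log2 level of the cDC2 markers was 4.36 with RT and anti-SIRPa against 5.59 with RT, and 5.34 against 5.52 in the pools with anti-PD-1, so 1 library carried most of the difference. In total 26 of 16933 genes passed edgeR's test, 21 higher and 5 lower, while DESeq2 passed 138 and RLE normalisation 85. With 1 pool left out the count was 3 without the RT pool, 1 without the RT and anti-PD-1 pool and 0 without either of the others, and edgeR with no filter or with all 20 libraries, or with the other antibody's term dropped, passed 0.

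Dendritic cell genes of CD11c+CD11b- cells were lower with anti-SIRPa. Siglech was at 85.7 ± 54.4 CPM with the antibody against 202 ± 42.4 CPM without it (n = 2 pools each), a log2 difference of -1.40 ± 0.19 (edgeR adjusted p = 0.0413). Dntt fell by 1.56 (SE 0.21, edgeR adjusted p = 0.0413), and the chemokine receptor Ccr9 fell by 1.33 (SE 0.18, edgeR adjusted p = 0.0413). Enpp2 rose by 1.10 ± 0.14 (edgeR adjusted p = 0.0413) and Has2, a hyaluronan synthase, by 1.07 ± 0.15 (edgeR adjusted p = 0.0413). Both belong to the same 287 genes, which held 1.77% of counts here with RT and anti-SIRPa against 1.14% with RT, and 0.808% against 0.595% in the pools with anti-PD-1. Of 7 plasmacytoid dendritic cell markers 3 fell, and 7 did when adjusted over the list alone (camera adjusted p = 4.07e-16, and adjusted p = 0.692 with an estimated correlation). Of 11 MHC class II genes 2 fell, and 11 on the list alone (camera adjusted p = 6.08e-20, and adjusted p = 0.692 with an estimated correlation). Of 10 CCR7 mature dendritic cell markers 4 fell (camera adjusted p = 1.96e-14, and adjusted p = 0.692 with an estimated correlation), and of 11 cDC1 markers the sorting nexin gene Snx22 fell by 1.13 (camera adjusted p = 2.57e-13, and adjusted p = 0.692 with an estimated correlation). NK cell markers moved the other way, 4 of 7 higher on the list alone (camera adjusted p = 0.00195, and adjusted p = 0.692 with an estimated correlation), and CD8 T cell markers had camera adjusted p = 0.0625. The fall was larger between the pools without anti-PD-1, with plasmacytoid dendritic cell markers at a mean log2 level of 4.99 with RT and anti-SIRPa against 6.17 with RT, and 5.86 against 6.55 in the pools with anti-PD-1. By pool, Siglech was at 11 CPM untreated, 172 with RT, 47.3 with RT and anti-SIRPa, 232 with RT and anti-PD-1 and 124 with both. In total 145 of 16603 genes passed edgeR's test, 45 higher and 100 lower, RLE normalisation passed 389 and DESeq2 301. The count was 0 without any 1 of the 4 pools, with no filter, with the other antibody's term dropped and with all 20 libraries in 1 fit, and 8 with a filter on mean CPM.

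In CD11c-CD11b+ cells edgeR's test passed 0 of 17118 genes for anti-SIRPa, with 853 at an unadjusted p under 0.05 and 12 passing DESeq2. The count was 1 without the RT pool and 1 without the RT and anti-PD-1 pool. The chemokine list was lower (camera adjusted p = 6.99e-07, and adjusted p = 0.843 with an estimated correlation), the proliferation list higher (camera adjusted p = 1.05e-06, and adjusted p = 0.843 with an estimated correlation) and the neutrophil markers higher, with S100a9 at 1.06 (camera adjusted p = 0.00317, and adjusted p = 0.843 with an estimated correlation). The mean log2 level of the neutrophil markers was 6.13 with RT and anti-SIRPa against 4.33 with RT. In the pools with anti-PD-1 it went the other way, at 4.77 with anti-SIRPa against 5.27 without, so 1 library carried the rise. Without the RT and anti-SIRPa pool S100a9 turned to -0.22 and Sirpa to 0.02. For the interaction of anti-SIRPa with population edgeR's test passed 0 of 20382 genes, with 1793 at an unadjusted p under 0.05, while RLE normalisation passed 0 and the fit without the CD8 T libraries 2. Sirpa itself had edgeR adjusted p = 0.497 in the test over all 4 populations.

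With anti-PD-1, CD8 T libraries of irradiated tumours held more transcripts of killing and of inhibitory receptors, and more of the CD8 T cell markers. Gzma was at 133 ± 13.6 CPM against 39.9 ± 10.8 (n = 2 pools each), a log2 difference of 1.74 ± 0.09 (edgeR adjusted p = 0.000215). Gzmk, another granzyme, rose by 1.04 ± 0.11 (edgeR adjusted p = 0.00192), Icos, an inducible costimulator, by 1.01 ± 0.07 (edgeR adjusted p = 0.000422) and Penk, the enkephalin precursor, by 1.23 ± 0.17 (edgeR adjusted p = 0.00559). Pdcd1 rose from 249 ± 24.8 to 345 ± 4.81 CPM (0.46 ± 0.07, edgeR adjusted p = 0.00939). H19, an imprinted long noncoding RNA of fetal tissue (chromosome 7, 142575529 to 142578143), fell from 143 ± 16.8 to 42.1 ± 7.89 CPM (-1.78 ± 0.08, edgeR adjusted p = 0.000104). Of 17 cytotoxicity genes 13 rose and none fell, with Prf1 at 0.89 (camera adjusted p = 8.1e-24, and adjusted p = 0.598 with an estimated correlation). Of 16 exhaustion genes 11 rose, with Tox at 0.75, Lag3 at 0.72 and Tigit at 0.64 (camera adjusted p = 6.45e-14, and adjusted p = 0.598 with an estimated correlation). All 12 CD8 T cell markers rose, with Cd8a at 0.60 (camera adjusted p = 5.54e-17, and adjusted p = 0.598 with an estimated correlation). Their mean log2 level was 8.74 and 8.64 with anti-PD-1 against 8.26 and 8.25 without it. For the exhaustion list it was 6.97 and 6.85 against 6.51 and 6.56, and for the cytotoxicity list 7.68 and 7.52 against 7.19 and 6.98. A change per T cell was not separated from a larger share of T cells in the sort.

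Markers of other cells fell in the CD8 T libraries with anti-PD-1. Of 12 macrophage markers 10 fell, with C1qa at -0.93 (camera adjusted p = 1.17e-12, and adjusted p = 0.598 with an estimated correlation). Of 8 stromal and endothelial markers 3 fell, with the pericyte receptor Pdgfrb at -1.25 (camera adjusted p = 2.95e-05, and adjusted p = 0.598 with an estimated correlation), and of 5 erythroid markers 4 fell (camera adjusted p = 4.39e-07, and adjusted p = 0.598 with an estimated correlation). Sirpa fell by 0.81 (SE 0.16, edgeR adjusted p = 0.0199). In total 1481 of 16486 genes passed edgeR's test, 540 higher and 941 lower. DESeq2 passed 907 and the fit of all 20 libraries 711. The count was 6 with the other antibody's term dropped, 0 with no filter, 1 without the RT pool, 1 without the RT and anti-SIRPa pool, 87 without the RT and anti-PD-1 pool and 1174 without the pool of both.

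**Figure D3:**
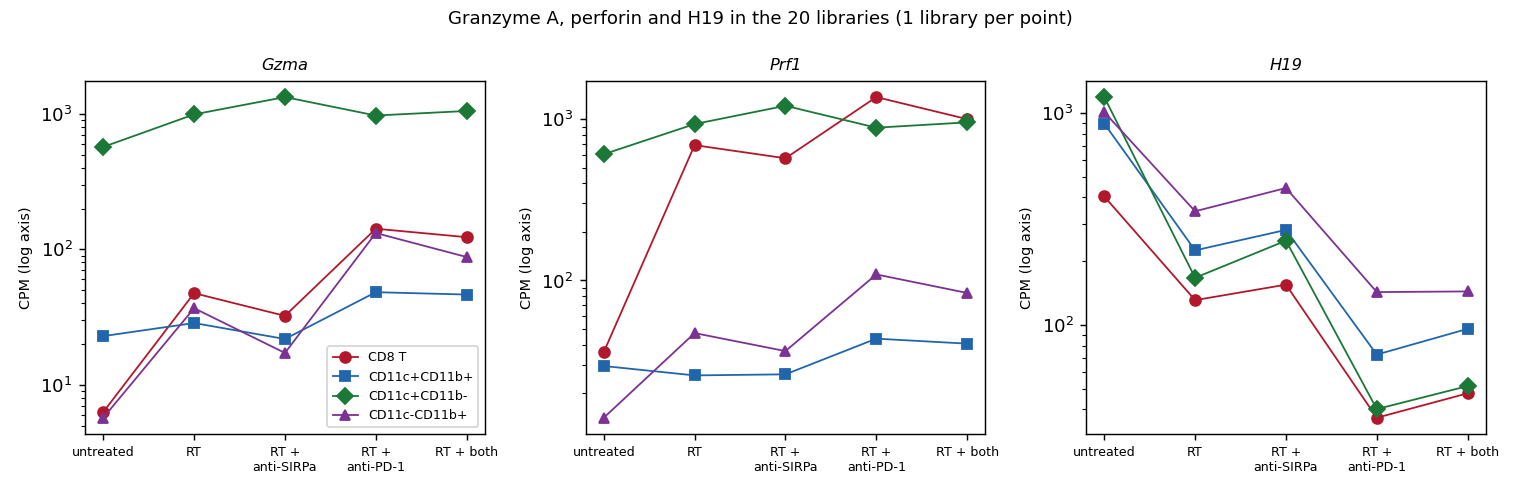
CPM on a log axis of Gzma, Prf1 and H19 (vertical) by treatment (horizontal) in the 4 populations, with 1 point per library and thin lines joining the libraries of a population. In CD8 T cells Gzma lies at 142 and 123 CPM in the 2 pools with anti-PD-1 against 47.5 and 32.3 CPM in the 2 irradiated pools without it, and H19 is lower with anti-PD-1 in each population.

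Anti-PD-1 in CD11c+CD11b+ cells went with lower proliferation genes and higher interferon gamma response genes. Of 23 proliferation genes 20 fell, with Ccnb1 at -1.02 and Cdk1 at -0.94 (camera adjusted p = 2.74e-26, and adjusted p = 0.756 with an estimated correlation). Of 21 interferon gamma response genes 7 rose, with the nitric oxide synthase Nos2 at 0.97 and Socs1 at 0.60 (camera adjusted p = 1.61e-08, and adjusted p = 0.756 with an estimated correlation). Cd274, which encodes the PD-1 ligand PD-L1 (chromosome 19, 29367455 to 29388095), rose from 340 ± 54.7 to 542 ± 76.3 CPM (n = 2 pools each, 0.71 ± 0.08, edgeR adjusted p = 0.00815). Flt3, a growth factor receptor of dendritic cells, rose by 1.21 ± 0.23 (edgeR adjusted p = 0.0272), and Il7r, the interleukin 7 receptor, by 1.06 ± 0.13 (edgeR adjusted p = 0.00853). Of 10 CCR7 mature dendritic cell markers 3 rose, with the amino acid oxidase Il4i1 at 2.17 (camera adjusted p = 6.02e-08, and adjusted p = 0.756 with an estimated correlation). Their mean log2 level was 6.37 with RT, 5.58 with RT and anti-SIRPa, 6.78 with RT and anti-PD-1 and 6.58 with both. The library of RT and anti-SIRPa thus carried much of the difference. The desaturase gene Fads2 fell by 1.83 (SE 0.24, edgeR adjusted p = 0.0101). H19, followed into the myeloid populations after its values were seen, fell by 1.55 (SE 0.08, edgeR adjusted p = 0.00344). The group of 287 genes, chosen for falling here, held 0.743% of counts with RT and anti-PD-1 against 1.26% with RT, and 1.03% against 1.89% in the pools with anti-SIRPa. Of 8 stromal and endothelial markers 3 fell and 1 rose (camera adjusted p = 0.0936). In total 1498 of 16933 genes passed edgeR's test, 524 higher and 974 lower, and DESeq2 passed 1209. The count was 1 with the other antibody's term dropped, 0 with no filter, 936 with all 20 libraries in 1 fit, 194 without the RT pool, 3 without the RT and anti-PD-1 pool and 0 without either pool that received anti-SIRPa.

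Dendritic cell markers were higher with anti-PD-1 in CD11c+CD11b- cells, and 1 library carried most of the difference. Of 10 CCR7 mature dendritic cell markers 7 rose, with Ccr7 at 0.62 (camera adjusted p = 2.2e-06, and adjusted p = 0.747 with an estimated correlation), and of 7 plasmacytoid dendritic cell markers 5 rose, with Siglech at 0.94 (camera adjusted p = 0.000253, and adjusted p = 0.747 with an estimated correlation). Of 11 cDC1 markers 4 rose, with Cadm1 at 0.96 and Wdfy4 at 0.90 (camera adjusted p = 4.05e-06, and adjusted p = 0.747 with an estimated correlation), and of 9 costimulation genes Cd86 and Cd80 rose by 0.83 and 0.82 (camera adjusted p = 0.000603, and adjusted p = 0.747 with an estimated correlation). The mean log2 level with RT, RT and anti-SIRPa, RT and anti-PD-1, and both was 6.91, 5.86, 7.21 and 6.91 for cDC1 markers, 7.35, 6.57, 7.68 and 7.36 for CCR7 mature dendritic cell markers, and 6.17, 4.99, 6.55 and 5.86 for plasmacytoid dendritic cell markers. The pool of both antibodies was thus level with RT alone for the first lists and lower for the last. Neat1, a long noncoding RNA of nuclear paraspeckles, rose from 276 ± 89.6 to 768 ± 68.5 CPM (n = 2 pools each, 1.54 ± 0.18, edgeR adjusted p = 0.00429). H19 fell by 2.14 (SE 0.10, edgeR adjusted p = 0.000287), and Nedd4, whose counts are uncertain, differed by -3.97 ± 0.12 (edgeR adjusted p = 2.77e-05). Rpph1, the RNA of ribonuclease P, fell by 2.42 (SE 0.17, edgeR adjusted p = 0.00163). Of 8 stromal and endothelial markers 5 fell, with Col3a1 at -1.50 (camera adjusted p = 0.000169, and adjusted p = 0.747 with an estimated correlation), and 5 of 12 macrophage markers fell with them (camera adjusted p = 3.16e-06, and adjusted p = 0.747 with an estimated correlation). In total 1696 of 16603 genes passed edgeR's test, 709 higher and 987 lower, and DESeq2 passed 1078. The count was 1 with the other antibody's term dropped, 0 with no filter, 1115 with a filter on mean CPM, 976 with all 20 libraries in 1 fit, 241 without the RT and anti-SIRPa pool and 0 without either pool that received anti-PD-1.

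Anti-PD-1 in CD11c-CD11b+ cells passed edgeR's test in 0 of 17118 genes, with 2950 at an unadjusted p under 0.05 and 570 passing DESeq2. Gzma was at 110 ± 31.5 CPM against 27.0 ± 13.8 (n = 2 pools each, log2 difference 2.12 ± 0.16, edgeR adjusted p = 0.125), Ncr1 differed by 1.72 ± 0.24 (edgeR adjusted p = 0.125), Cd274 by 0.93 ± 0.16 (edgeR adjusted p = 0.125) and H19 by -1.42 ± 0.15 (edgeR adjusted p = 0.125). Of 17 cytotoxicity genes 11 were higher when adjusted over the list alone, with Prf1 at 1.23 (camera adjusted p = 1.64e-20, and adjusted p = 0.659 with an estimated correlation), and so were 5 of 7 NK cell markers (camera adjusted p = 4.2e-14, and adjusted p = 0.659 with an estimated correlation) and all 12 macrophage markers, with Apoe at 0.92 (camera adjusted p = 5.02e-13, and adjusted p = 0.659 with an estimated correlation). Of 23 proliferation genes 21 were lower on the same count, with Aurkb at -0.83 (camera adjusted p = 7.62e-17, and adjusted p = 0.659 with an estimated correlation). Without the RT pool 3242 genes passed, without the RT and anti-SIRPa pool 59, without the RT and anti-PD-1 pool 1 and without the pool of both 36, and the fit of all 20 libraries passed 1072.

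The interaction of anti-PD-1 with population passed edgeR's test for 273 of 20382 genes. Zmynd15, Cd74, Lifr, H2-Aa, Ciita and Prf1 each had edgeR adjusted p = 0.0441, Gzma and Gzmb had edgeR adjusted p = 0.0442, and Sirpa had edgeR adjusted p = 0.0475. The count was 11 with RLE normalisation, 0 with no filter and 436 with a filter on mean CPM, and without the CD8 T libraries 1 gene passed for a difference among the 3 myeloid populations (edgeR adjusted p = 0.00235).

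Cd47, the ligand of SIRPa, passed in none of the 12 tests of a treatment: its log2 differences ran from 0.24 to 0.46 for irradiation (smallest edgeR adjusted p = 0.122), from -0.27 to -0.06 for anti-SIRPa (smallest edgeR adjusted p = 0.599) and from 0.10 to 0.32 for anti-PD-1 (smallest edgeR adjusted p = 0.159). Sirpa did not pass in the 4 tests of anti-SIRPa either, with differences from -0.62 to -0.02 (smallest edgeR adjusted p = 0.0902). Cd274 passed for anti-PD-1 in CD11c+CD11b+ cells and in CD11c+CD11b- cells, where it rose by 0.56 (edgeR adjusted p = 0.0233).

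The triple combination was compared with RT alone as 1 library against 1 in each population. These ratios have no replicate check, and their intervals cover counting error only. Percentiles of gene lists are set against lists of random genes, which need not move together. They describe these libraries and are not a test of the treatment. In CD8 T cells 75 of 9928 genes at 10 CPM or more differed 2-fold or more, 29 higher and 46 lower. Dgkz, a diacylglycerol kinase, was 2.95-fold higher (95% interval 2.79 to 3.13), and Nedd4, with uncertain counts, 12.4-fold higher (10.9 to 14.1). The median log2 ratio of the cytotoxicity list was 0.52, at percentile 100 of 10000 random lists matched on expression, and that of the exhaustion list 0.36, at percentile 100. CD8 T cell markers were higher too, at a mean log2 level of 8.64 against 8.26 with RT. A change per T cell was thus not separated from a larger share of T cells. Macrophage markers had a median of -0.58, at percentile 0, and MHC class II genes of -0.51, at percentile 0. In CD11c+CD11b+ cells 53 of 9834 genes differed 2-fold or more, 25 higher and 28 lower. Dgkz was 3.31-fold higher (3.06 to 3.60) and H19 was at 0.427 of its level with RT (0.409 to 0.446). The interferon gamma response list had a median of 0.24, at percentile 100, and the proliferation list of -0.25, at percentile 0.

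In CD11c+CD11b- cells 157 of 10085 genes differed 2-fold or more between the triple combination and RT, 68 higher and 89 lower. Neat1 was 3.38-fold higher (3.28 to 3.48). Macrophage markers had a median of -0.74, at percentile 0, plasmacytoid dendritic cell markers of -0.35, at percentile 0.2, and CD8 T cell markers of 0.21, at percentile 99.8. In CD11c-CD11b+ cells 62 of 9908 genes differed 2-fold or more, 35 higher and 27 lower. Gzma was 2.39-fold higher (2.21 to 2.58), at 87.8 against 36.8 CPM, and Cd38, an ectoenzyme of activated immune cells, 2.24-fold higher (1.96 to 2.56). NK cell markers had a median of 0.96, at percentile 100, the cytotoxicity list of 0.65, at percentile 100, and the proliferation list of -0.33, at percentile 0. RT with anti-PD-1 alone differed 2-fold or more from RT in 496, 305, 348 and 180 genes of CD8 T, CD11c+CD11b+, CD11c+CD11b- and CD11c-CD11b+ cells, and RT with anti-SIRPa alone in 67, 115, 326 and 186 genes. Differences between these counts were not tested. The counts of the triple combination against RT depended on the expression limit: at 1 CPM or more they were 798, 503, 1430 and 648 in the same order, and at 50 CPM or more 15, 15, 35 and 16.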

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

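All tests of explanations in this part were chosen after results were seen, except that of overlapping gene models, which was planned before.

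The library labelled untreated CD8 T held macrophage genes in place of CD8 T cell genes. Its 12 CD8 T cell markers lay at a median of 4.82% of the mean of the other 4 CD8 T libraries, and the SD of their log2 ratios was 0.25, so they were reduced by a common factor, which fits few CD8 T cells in the sort with macrophages in their place. A swap with another library of this series is excluded, because 0 of the 15 myeloid libraries reached the other CD8 T libraries in these markers. A mixture with the myeloid fractions of the same pool, each taken whole, is excluded too. The 12 macrophage markers were at a median of 2.48 times the highest of the 3 other untreated libraries. Those fractions held other cell types as well, so this test does not exclude macrophages of the same pool. A tube from outside this series was not tested and stays open. Irradiation in CD8 T cells cannot be told apart from the make-up of this library.

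A group of 287 genes was lower with anti-PD-1 in CD8 T, CD11c+CD11b+ and CD11c+CD11b- cells, where 3.86 would be if the populations were independent, and 15 genes were higher, where 0.707 would be. The lower group included H19, Col3a1, Pdgfra and Yap1, with 3 stromal and 0 epithelial tumour cell markers. It also held Mmp9 of the neutrophil list, Cd63 of the lysosome list, Fcrls and Tmem119, so its members were not stromal genes only. The populations come from the same pools and are not independent. The mean of the group in each library was subtracted first, so differences in its level as a whole were removed. That level did differ, from 1.06 to 2.1% of counts between the 4 populations of the RT pool. The SD that remained within a pool was at a median 0.443 of that of other genes of like level. For the 15 higher genes chosen in the same way this share was 1.65. The other genes were centred only on the mean of all other genes, so the 2 sides were not measured alike. At the median the lower genes kept their levels relative to each other between populations, but Fcrls and Tmem119, with SDs of 1.32 and 1.6, did not. The share met the bound set for non-immune RNA carried into every sort. That centring favours any group that varies together, so the share does not decide it. The ratio of Col3a1 to H19 was 3.02 to 3.68 in the RT pool, 4.17 to 4.72 untreated, 4.52 to 4.74 with RT and anti-SIRPa, 5.56 to 6.28 with RT and anti-PD-1 and 5.83 to 7.42 with both, so such a source did not have 1 make-up in all pools. Separate regulation in each cell type is neither shown nor excluded. Of these genes, 40.8% had an SD below the lowest 1 in 20 of other genes, with the same unlike centring. The bound for that test was set after the value was seen.

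Some genes, such as Nedd4 and Kctd12, stood at 2 far levels among irradiated libraries of 1 population. Of 22 such genes, 36.4% came under 2-fold once overlapping gene models were summed, against 1.83% of 219 reference genes. The planned bound was not reached, and the reference genes were not matched on having an overlapping model. Allocation of reads between overlapping models is thus neither shown nor excluded. Of the 22, 17 had an overlapping model, and the others had none to sum. Nedd4 in CD8 T cells went from a log2 range of 4.22 to 3.86 and Kctd12 in CD11c+CD11b+ cells from 9.89 to 8.4, so summing did not bring these 2 under 2-fold, and what sets their levels was not tested.

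A gap test set 1 library apart from the other 4 of its population in 10 of 72 tests, where 3.6 would be by chance at 1 in 20. For the CD8 T cell markers the gap ratio was 0.893 in untreated CD8 T cells and 0.716 in untreated CD11c+CD11b- cells. CD4 and regulatory T cell markers gave 0.783 in untreated CD8 T cells and 0.819 in untreated CD11c-CD11b+ cells. NK cell markers gave 0.870 in untreated CD8 T cells, and the percent of mitochondrial counts gave 0.758 there. Macrophage markers gave 0.826 in untreated CD11c+CD11b+ cells. Inflammatory monocyte markers gave 0.898 in untreated CD11c+CD11b+ cells and 0.8 in untreated CD11c-CD11b+ cells. The cDC2 markers gave 0.756 in CD11c+CD11b+ cells of the RT and anti-SIRPa pool.

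The interaction tests passed edgeR for 4207 genes for irradiation and 273 for anti-PD-1. Without the CD8 T libraries most of the first and all of the second were lost. Transcripts not matched to the annotation held at most 0.40% of the counts of a library.

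To ask about chance, the libraries of each population comparison were split in other ways. For the 2 comparisons within myeloid cells, which are paired by pool, 16 splits part every pool as the real one does, which is too few for a share under 1 in 20. Of these 16, 1 split, the real one, called as many as 8510 genes for CD11c+CD11b- against CD11c+CD11b+ cells, and the highest other called 0. For CD11c+CD11b+ against CD11c-CD11b+ cells it was again 1, the real one, with 4676 genes, and the highest other called 0. Splits that part fewer pools were also drawn, and the highest called 1 and 2 genes. For CD8 T against myeloid cells, 1 of 60 splits, the real one, called as many as 7226 genes and the highest other called 3095. For CD8 T against myeloid cells the share was thus under 1 in 20 at this number of splits. The cells were sorted on the surface markers that define the populations, so a high count for the real split was built into the design. With 4 irradiated pools against 1, taking any other pool as the lone one called 0 genes in every population, which decides nothing, because the untreated library then adds to the spread of the 4 and 5 arrangements allow no share under 1 in 5.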

How the results depend on the processing

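Most alternatives were fixed before the data were examined, and the filter on mean CPM, the removal of the library labelled untreated CD8 T and the removal of all CD8 T libraries were chosen after results were seen. Numbers of genes that passed are given for each comparison, and the cause of a change was not tested. The population comparisons were paired by treatment pool, which entered the fit as a term.

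Between populations, CD11c+CD11b- against CD11c+CD11b+ cells gave 8510 genes, and 6794 to 9529 in leave-one-out fits. CD11c+CD11b+ against CD11c-CD11b+ cells gave 4676 genes, 955 with no pool term, and 2860 (without the RT pool) to 4850 in leave-one-out fits. CD8 T against myeloid cells gave 7226 genes, and in leave-one-out fits 4240 (without the pool of both antibodies), 4359 (without the RT pool), 4492 (without the RT and anti-PD-1 pool) and up to 10550 (without the untreated pool). With only the library labelled untreated CD8 T removed the count was 10603.

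For irradiation in CD8 T cells the count of 5048 ran from 3726 to 5667 in leave-one-out fits. The count of 147 in CD11c+CD11b+ cells became 4 with no low-count filter, 81 with the mean CPM filter, 1268 with DESeq2 and 2342 with antibody terms, and 124 with all 20 libraries in 1 fit, of which 42 were among the 147. Leave-one-out fits there gave 0 without the RT pool, 1 without the pool of both, 306 without the RT and anti-PD-1 pool and 1910 without the RT and anti-SIRPa pool. For CD11c+CD11b- cells 3 genes became 0 with no low-count filter, 2674 with DESeq2, 2779 with antibody terms and 2096 with all 20 libraries in 1 fit, and 0 to 3200 in leave-one-out fits, the highest without the RT and anti-SIRPa pool. The count of 0 in CD11c-CD11b+ cells became 1 with the mean CPM filter, 1400 with DESeq2 and 646 with all 20 libraries in 1 fit. Leave-one-out fits there gave 0 to 3941, the highest without the RT and anti-SIRPa pool, and 2 without the RT and anti-PD-1 pool.

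For anti-SIRPa in CD8 T cells the count of 28 became 11 with RLE normalisation, 0 with no low-count filter, 60 with DESeq2, 0 with all 20 libraries in 1 fit and 1 with the other antibody's term dropped. The mean CPM filter passed 28 as well, of which 19 were the same. Leave-one-out fits gave 10, 1, 2 and 0 without the RT pool, the RT and anti-SIRPa pool, the RT and anti-PD-1 pool and the pool of both. For CD11c+CD11b+ cells 26 genes became 85 with RLE normalisation, 138 with DESeq2, 0 with no low-count filter, 0 with all 20 libraries and 0 with the term dropped, and 3, 0, 1 and 0 in leave-one-out fits in the same order. The count of 145 in CD11c+CD11b- cells became 389 with RLE normalisation, 301 with DESeq2, 8 with the mean CPM filter, 0 with no low-count filter, 0 with all 20 libraries and 0 with the term dropped, and 0 in all 4 leave-one-out fits. For CD11c-CD11b+ cells 0 genes became 12 with DESeq2, and 1, 0, 1 and 0 in leave-one-out fits in the same order.

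For anti-PD-1 in CD8 T cells the count of 1481 became 0 with no low-count filter, 907 with DESeq2, 711 with all 20 libraries in 1 fit and 6 with the other antibody's term dropped, and 1, 1, 87 and 1174 in leave-one-out fits in that order. The count of 1498 in CD11c+CD11b+ cells became 0 with no low-count filter, 936 with all 20 libraries and 1 with the term dropped, and 194, 0, 3 and 0 in leave-one-out fits. For CD11c+CD11b- cells 1696 genes became 0 with no low-count filter, 1115 with the mean CPM filter, 1078 with DESeq2, 976 with all 20 libraries and 1 with the term dropped, and 2149, 241, 0 and 0 in leave-one-out fits. The count of 0 in CD11c-CD11b+ cells became 570 with DESeq2 and 1072 with all 20 libraries, and 3242, 59, 1 and 36 in leave-one-out fits. These leave-one-out fits also dropped the other antibody's term, so the 2 changes are not separated.

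Of the interactions with population, that of irradiation fell from 4207 genes to 2440 with no low-count filter and to 169 with CD8 T libraries removed. That of anti-SIRPa went from 0 to 2 with CD8 T libraries removed. That of anti-PD-1 went from 273 to 11 with RLE normalisation, 0 with no low-count filter, 436 with the mean CPM filter and 1 with CD8 T libraries removed. In the single-library ratios of the triple combination to RT, counts of 2-fold genes of 75, 53, 157 and 62 in CD8 T, CD11c+CD11b+, CD11c+CD11b- and CD11c-CD11b+ cells became 798, 503, 1430 and 648 with at least 1 CPM in either library, and 15, 15, 35 and 16 with at least 50 CPM.

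Of 1429 values of named genes under an alternative, 974 kept their direction and side of the limit, 372 lost the limit, 79 gained it and 4 turned direction. The 4 were all for anti-SIRPa in leave-one-out fits: in CD8 T cells, Col3a1 ran from -0.04 (without the RT and anti-SIRPa pool) to 1.23 and Gzmb from -0.92 to 0.07 (without the RT and anti-PD-1 pool), and in CD11c-CD11b+ cells, S100a9 ran from -0.22 to 2.28 and Sirpa from -0.7 to 0.02, with both turning without the RT and anti-SIRPa pool. Of 535 list tests, 262 lost the limit with an estimated inter-gene correlation and 273 kept their side. Residual degrees of freedom were few, 1 for an antibody and 3 for irradiation, and the power of that setting was not tested, so losses there decide nothing. Lists were lost in the population comparisons as well, so passes at the preset correlation alone depend on that setting.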

Other observations

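The spread within a pool and the ratio of Col3a1 to H19 in this part were chosen after results were seen, while the comparisons and leave-one-out fits were planned before. The sorted fractions held more than 1 cell type. The CD11c+CD11b- cells carried NK cell, plasmacytoid dendritic cell and cDC1 genes together, with Ncr1 at 259 ± 37.4 CPM (n = 5 pools) against 7.08 ± 2.12 CPM in CD11c+CD11b+ cells. Changes of a gene list in this fraction can thus be changes in the share of a cell type.

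The CD11c-CD11b+ cells held neutrophil genes at levels that varied between pools, with S100a8 at 179 CPM untreated, 99.4 with RT, 706 with RT and anti-SIRPa, 324 with RT and anti-PD-1 and 164 with both. Granzyme and perforin transcripts were higher with anti-PD-1 in this fraction beside NK cell markers without passing over all genes, and Gzma was at 132 CPM in the RT and anti-PD-1 pool against 36.8 CPM with RT alone.

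A first hypothesis is that type I interferon genes of tumour macrophages stay raised 5 days after irradiation whichever antibody is given. Trex1 in CD11c+CD11b+ cells was at 73.4, 70.8, 72 and 79 CPM in the 4 irradiated pools against 18.6 CPM untreated. Macrophage markers rose in the same libraries, from a mean log2 level of 8.48 untreated to 9.19 to 9.34 irradiated. A change in the share of macrophages was thus not separated. The hypothesis would be tested with 3 or more untreated and irradiated pools, with Trex1, Cxcl11 and Irf7 measured in macrophages sorted by F4/80. It would be refuted by overlap of the untreated and irradiated levels.

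A second hypothesis is that RNA of tumour or stromal cells enters every sort. Once the mean of the group in each library was subtracted, the genes lower with anti-PD-1 had a spread within a pool of 0.443 of that of other genes of like level. For the 15 genes that were higher this share was 1.65. The other genes were centred on a mean of their own, so the 2 sides were not measured alike and the share does not decide the hypothesis. The ratio of Col3a1 to H19 was 3.02 to 3.68 with RT, below the 5.56 to 6.28 with RT and anti-PD-1 and the 5.83 to 7.42 with both antibodies, while it overlapped between the last pair and between the untreated pool (4.17 to 4.72) and that of RT and anti-SIRPa (4.52 to 4.74). No single gene thus stands for the amount of such a source. It would be tested by sorting with a tumour-cell dye, or by adding tumour RNA in known amounts, and following these genes in each sort.

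Another hypothesis is that anti-SIRPa with RT lowers the share of plasmacytoid dendritic cells in the CD11c+CD11b- fraction. Siglech and 2 more of the 7 markers fell in the fit of 4 pools, but the count of genes that passed was 145 there and 0 with only the other antibody's term dropped. With the term kept, the count was 8 with a filter on mean CPM, 1 of them among the 145. It was 0 with no low-count filter and 0 with all 20 libraries in 1 fit. The finding thus depends on the term and on the filter. Leave-one-out fits also dropped the term, so the part of any 1 pool is not separated. Counting Siglec-H+ cells by flow cytometry in single tumours would test it.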
